A study of Mus musculus with 12 samples.

How the data were processed

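Total RNA was measured in 12 libraries of mouse CD4 T cells, 3 for each of 4 groups: Th17 wild type, Th17 GLUT3-deficient, Th1 wild type and Th1 GLUT3-deficient. GLUT3 is the glucose transporter encoded by Slc2a3. Per the labels' protocols, naive T cells had been stimulated through CD3 and CD28 with polarizing cytokines for 3 days in culture, and the background was C57BL/6. Full-length cDNA was amplified from a small amount of total RNA with the SMART-Seq kit, fragmented and tagged with Nextera XT, and sequenced from 1 end only, per the labels' protocols. Such libraries do not mark the strand, so reads of a gene and of its antisense or overlapping partner are not separated. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt, STAR 2.7.2b, featureCounts 1.6.4 of the Subread package, DESeq2 1.24.0 and the build GRCm38.p6, without saying how each was used.

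The authors deposited 1 table per lineage with 45703 genes each, and the values are TPM, read counts divided by exon length and scaled to the same total in every library, by the names of the tables and by their sum of 1000000 in every library. The tables write decimals with a comma, and they hold no read counts. The planned count test was therefore replaced by the test that the design had set for TPM. Each gene row also gives its coordinates and combined exon length. Gene starts equalled those of the RefSeq annotation of GRCm38.p6 for 45701 of the 45703 genes, and coordinates are given in that build. TPM multiplied by exon length came out as whole multiples of 1 value per library, within 0.02 reads, for 100.0% of the values in every library. The reads recovered this way numbered 16596283 to 28496606 per library. A gene with 1 kb of exon and 3 reads would stand at 0.19 to 0.44 TPM, which covers counting error only, since PCR copies are not independent molecules. No 2 libraries of a group agreed within sampling noise: the chi-square per gene between replicates was at least 13.2.

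Groups and replicate numbers came from the sample titles. The labels do not say that replicates are separate animals or separate cultures, so the p-values measure only the spread between these libraries, which may be in part technical. Genes at 1 TPM or more in at least 3 of the libraries of a fit were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model per gene, moderated with a mean-variance trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. The genotypes were compared within each lineage on its 6 libraries. The difference between the genotype effects of the 2 lineages, and Th17 against Th1 within each genotype, were tested in a model of the 4 group means over all 12 libraries.

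In addition, 49 gene lists on metabolism, helper T cell lineages, signalling, stress, cell cycle and markers of other cell types were fixed before the data were examined, together with the groups, the tests and a set of alternative settings. Of 1148 list entries, 1107 matched by symbol, 25 by an older symbol and 16 not at all. Lists with at least 5 tested genes were tested with camera in limma at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction. Members of a list were counted after adjustment over all genes tested and after adjustment over the list alone.

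The genes named were set by a rule fixed in advance. It takes 21 key genes, and the 10 largest rises and 10 largest falls per genotype comparison among genes that passed the test, averaged at least 5 TPM, had every library of 1 genotype above every library of the other and carried a named symbol. It also takes the 4 members of each list with the smallest adjusted p, 5 genes for the interaction by adjusted p, and the 5 largest differences in each direction between lineages in wild type. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

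Replicate numbers recur in every group. Deviations from the group means correlated between the same-numbered Th17 libraries of both genotypes at 0.14, 0.41 and 0.23 for numbers 1, 2 and 3, and between the wild-type Th17 and Th1 libraries at 0.72, 0.26 and 0.53. All exceed 0.1, so for these comparisons the numbers were taken to pair the libraries, on this correlation alone, and a fit with the number as a block was an alternative. Libraries of different numbers correlated at -0.41 to 0.11 and at -0.61 to 0.28 in these comparisons, so some of them exceed 0.1 too. Deviations within a group cancel out, so the correlations depend on each other and the pairing is not certain.

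The steps were tested on simulated reads with 200 changed genes. Each gene was drawn on its own, without deviations shared across a library, a library that stands apart or a trend on length. The shares below therefore need not hold for the real libraries. In the Th17 genotype comparison, 13813 genes were tested and 1.6%, 42.6% and 77.8% of the genes changed 2-fold, 4-fold and 8-fold were recovered, with 10 false among 89 calls. In the Th1 comparison, with 13423 genes, the shares were 27.5%, 82.6% and 95.9%, with 9 false among 151 calls. For the interaction, with 14489 genes, they were 5.4%, 40.7% and 58.3%, with 8 false among 71 calls. Alternatives planned in advance covered the pseudocount, the filter, the replicate block, the samples in the model, the mitochondrial genes and each library left out. Median-of-ratios scaling, voom on the recovered reads, weights per library and removal of trends on GC content and exon length were added after seeing the data. GC content was known for 94.7% of the genes. Figures were drawn with matplotlib 3.10.9.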

Results

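The data address how loss of the glucose transporter GLUT3 changes the transcriptome of T helper 17 (Th17) cells, which make interleukin 17, and of T helper 1 (Th1) cells, which make interferon gamma. Each lineage was measured in 3 wild-type and 3 GLUT3-deficient libraries after 3 days of activation and polarization in culture. The recovered reads numbered 19639099, 21414087 and 22563719 in the Th17 wild-type, 24048759, 16936787 and 28324216 in the Th17 GLUT3-deficient, 17119177, 19393771 and 17412231 in the Th1 wild-type, and 28496606, 18391202 and 16596283 in the Th1 GLUT3-deficient libraries. The first principal component held 43.2% of the variance and the second 25.3%. Th17 GLUT3-deficient replicate 2 stood apart from all others. Its median absolute log2 difference from the other libraries of its group was 0.62, against 0.14 to 0.42 for the other 11 libraries, and it bears on every Th17 GLUT3-deficient mean given here.

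**Figure D1:**
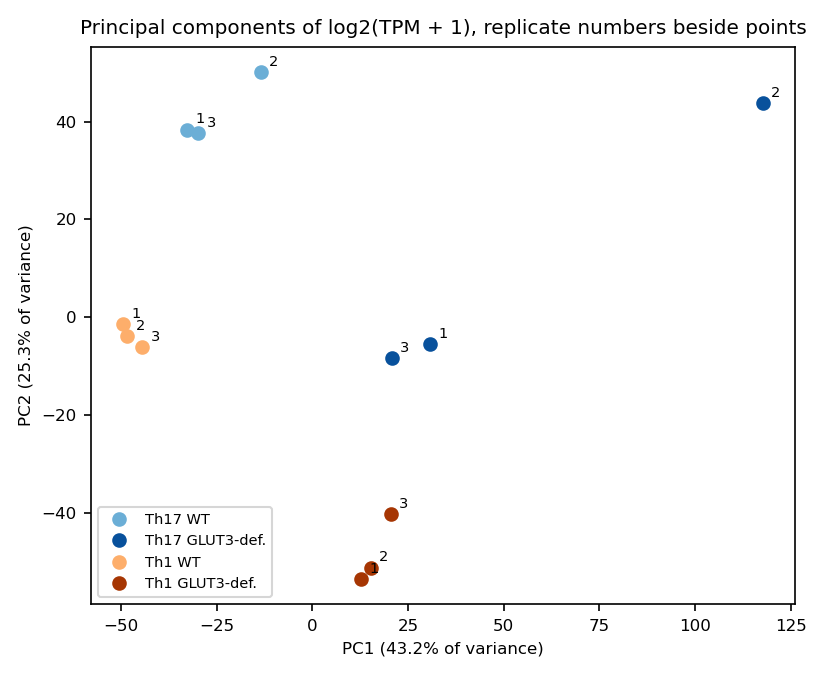
Scores of the 12 libraries on the first 2 principal components of log2(TPM + 1) over 14579 genes, 1 point per library, coloured by group. Th17 GLUT3-deficient replicate 2 lies at 117.7 on the first component, and the other 11 libraries lie between -49.4 and 30.8.

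The targeted gene, Slc2a3 (chromosome 6, 122727809 to 122802363), was lower in every GLUT3-deficient library than in every wild-type library of its lineage. In Th17 cells it stood at 379, 109 and 44.6 TPM in wild type and at 5.14, 18.8 and 3.30 TPM in the deficient libraries. In Th1 cells it stood at 398, 95.6 and 64.7 TPM in wild type and at 6.79, 4.49 and 7.97 TPM in the deficient libraries. The log2 fold change was -3.95 ± 0.85 (SE) in Th17 (limma adjusted p = 0.0369, 3 against 3 libraries) and -4.23 ± 0.57 in Th1 (limma adjusted p = 0.000901). The direction fits the genotype labels in all 12 libraries. Reads on parts of the gene that a deletion leaves in place would still count, and the labels do not say which part is missing. Of the genes named below, Il17re, Usp18, Cd4, Klrd1, Klrk1, Klrc1 and the neighbouring gene Necap1 lie within 10 Mb of Slc2a3. In Th17 the call was lost when any library other than GLUT3-deficient replicate 2 was left out, with log2 fold changes of -4.67 to -3.14 over the 6 fits.

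**Figure D2:**
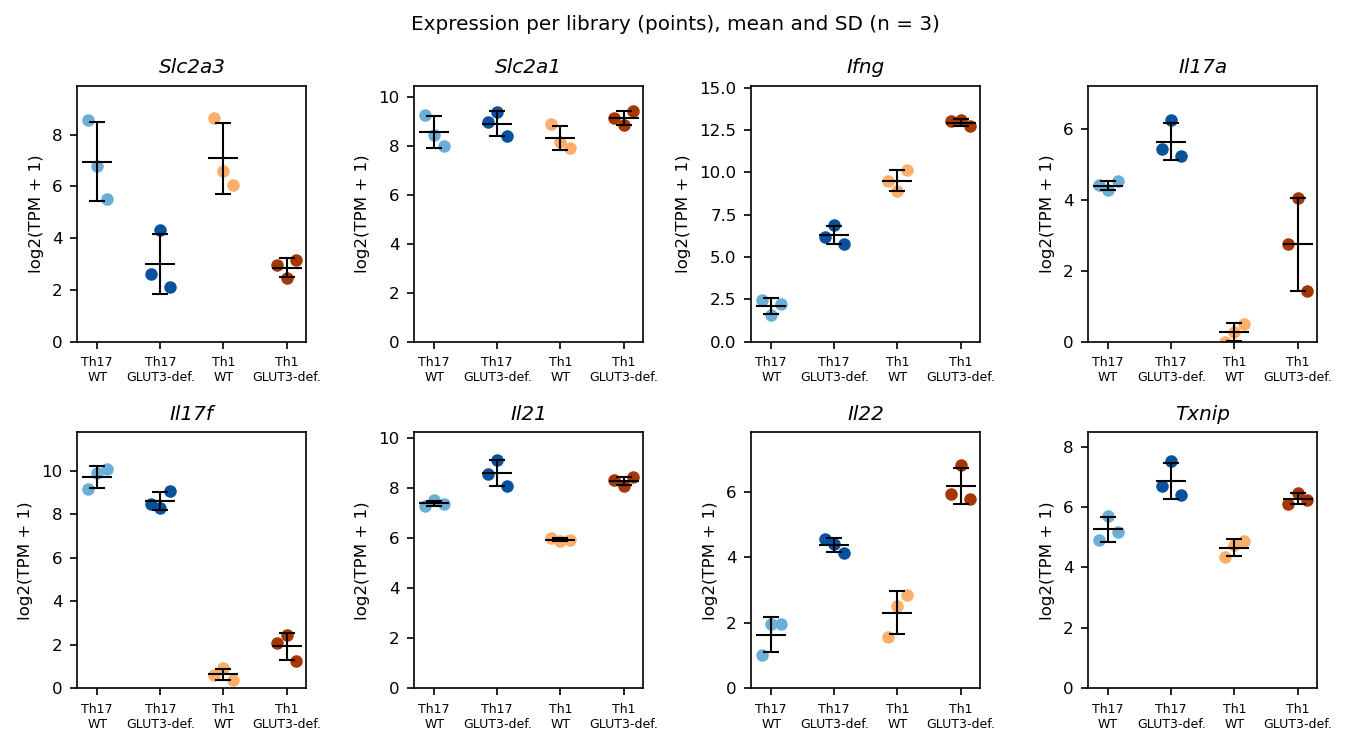
Expression of 8 genes fixed in advance as log2(TPM + 1), 1 point per library, with the mean and SD of each group of 3 libraries. Slc2a3 was lower and Ifng, Il21, Il22 and Txnip were higher in every GLUT3-deficient library than in every wild-type library of the same lineage.

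GLUT3-deficient Th17 libraries held far more transcript of genes of interferon signalling and of the Th1 program than wild-type Th17 libraries. Markers of other cells rose in the same libraries, with all 4 tested gamma delta T cell markers (median log2 fold change 3.31), 4 of 8 myeloid markers and 2 of 7 markers of CD8 and natural killer cells. So did 7 of 18 immediate early genes, a list fixed as sensitive to the handling of cells. Ifng, which encodes interferon gamma, rose from 3.47 ± 1.35 to 82.3 ± 33.0 TPM (mean ± SD, n = 3 each), a log2 fold change of 4.20. Ubd, an interferon-inducible ubiquitin-like protein, rose from 0.665 ± 0.625 to 80.6 ± 29.6 TPM, and the immunity-related GTPase Iigp1 from 0.409 ± 0.213 to 62.5 ± 33.7 TPM. Ifi211, Ifi205 and Ifi204, neighbouring members of the interferon-inducible p200 family on chromosome 1 between 173747293 and 174031755, rose by 5.63, 4.78 and 4.60 on the log2 scale, and as close paralogs their single values are uncertain. They adjoin Ifi207, which lay under 0.5 TPM in every wild-type library and above 1 TPM in every deficient library, as did Fcer1a and Slamf8 nearby. The remaining largest rises were Ccn3, Usp18 and Tnfrsf11b, with log2 fold changes of 4.11, 4.08 and 4.04, and Trdd2, a diversity segment of the T cell receptor delta locus, which was listed at 0 in every wild-type library and stood at 9.70, 36.4 and 11.9 TPM in the deficient libraries. With 16 bases of exon, these values of Trdd2 rest on 2, 4 and 3 reads.

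The largest falls in Th17 cells were in Acvrl1, a receptor of the TGF-beta family (-4.81), Slc2a3, Lbp (-3.57), Ramp1 (-3.36), Krt83 (-3.13), Timd2 (-2.95), Wdr54 (-2.85), Serpinb1a (-2.77), Cd24a (-2.64) and Gatm (-2.56, from 169 ± 29.8 to 27.6 ± 2.83 TPM). Limma adjusted p-values of these 20 genes ran from 0.00051 to 0.0369. The rule that named them took only genes whose groups did not overlap. Levels of Acvrl1 varied widely in wild type, at 61.7 ± 68.8 TPM. Acvrl1, Slc2a3 and Wdr54 were each highest in wild-type replicate 1. The calls of Wdr54 were lost without any library other than GLUT3-deficient replicate 2, those of Acvrl1 and Lbp without GLUT3-deficient replicate 1, and those of Lbp and Timd2 without wild-type replicate 2 or 3.

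Among the cytokine and metabolic genes fixed in advance, Il22 rose from 2.26 ± 1.07 to 20.0 ± 3.08 TPM (adjusted p = 0.00694), Il21 from 168 ± 13.2 to 405 ± 147 TPM (adjusted p = 0.0455) and Txnip, an inhibitor of glucose uptake, from 38.4 ± 11.6 to 123 ± 54.0 TPM (adjusted p = 0.0399), all by limma and in 3 of 3 libraries. The signature cytokines of the lineage did not pass the test: Il17a stood at 20.1 ± 1.83 TPM in wild type and 51.1 ± 20.3 TPM in deficient cells (adjusted p = 0.0528), and Il17f at 867 ± 266 and 404 ± 125 TPM (adjusted p = 0.0885). Tbx21, the Th1 master regulator, stood at 3.64 ± 1.16 and 36.9 ± 38.7 TPM (adjusted p = 0.0714), with 81.2 TPM in replicate 2. With the replicate number as a block the adjusted p was 0.0428 for Il17a, 0.0361 for Il17f and 0.019 for Tbx21, and over all alternatives it ran from 6.74e-05 to 0.201, from 4.84e-05 to 0.286 and from 5.11e-05 to 0.213. These ranges include the fit with weights per library, which did not converge. Slc2a1, which encodes GLUT1, stood at 404 ± 185 and 499 ± 163 TPM (adjusted p = 0.607). The other 12 key genes, among them Cd4, Il23r, Ccr6, Il2, Csf2, Foxp3, Hk2, Ldha, Acly, Myc and Hif1a, did not pass either, with log2 fold changes from -0.49 to 0.93. Cd4 was at 335 TPM in replicate 2 against 68.0 and 79.6 TPM in the other deficient libraries. Slc2a6, another sugar transporter, rose from 28.3 ± 9.06 to 71.3 ± 16.7 TPM (adjusted p = 0.0489). The calls of Txnip and Slc2a6 were lost without any library other than GLUT3-deficient replicate 2, that of Il21 without GLUT3-deficient replicate 1 or any wild-type library, and that of Il22 without GLUT3-deficient replicate 1.

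By fixed list, 26 of 36 interferon response genes rose in Th17 cells and 0 fell, or 29 when adjusted over the list alone, with a median log2 fold change of 1.98. Examples were Zbp1 (3.26), Isg20 (2.83) and Irf1 (2.71). Of 24 Th1 genes 13 rose, 16 when adjusted over the list alone, among them Gzmb (from 126 ± 36.6 to 1101 ± 252 TPM), Ccl4 (2.98) and Nkg7 (2.64). Of 18 immediate early genes, which respond quickly to receptor signals and to handling, 7 rose, 10 when adjusted over the list alone, with Btg2 (2.73) and Dusp2 (2.40). Of 26 cytokine genes 9 rose and 0 fell, 12 and 1 when adjusted over the list alone. Csf1 (3.33) and Tnfsf8 (2.51) were among those that rose. Of 26 genes of chemokines and migration 8 rose and 0 fell, 9 and 2 when adjusted over the list alone. Those that rose included Ccl20 (3.51), Ccl3 (3.01) and Ccl5 (1.96). Of 22 core Th17 genes 3 rose (Ccl20, Il22 and Il21) and 2 fell (Cd5l, -2.26, and Il17re, -1.48), 5 and 3 when adjusted over the list alone. Of 19 genes of a pathogenic Th17 program 7 rose and 0 fell, 8 and 1 when adjusted over the list alone. The call of Csf1 was lost without any wild-type library, that of Ccl5 without wild-type replicate 2 or 3 or GLUT3-deficient replicate 1 or 3, that of Cd5l without GLUT3-deficient replicate 1 or 3, and that of Il17re without any library other than GLUT3-deficient replicate 2.

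Of 42 ribosomal protein genes 3 fell over all genes, 17 when adjusted over the list alone. The 3 were Rpl3 (-1.12), Rps2 (-1.12) and Rpl14 (-1.17), and the median log2 fold change of the list was -0.80. The call of each of these 3 was lost with median-of-ratios scaling. Of 15 genes of serine and one-carbon metabolism 5 fell, 6 when adjusted over the list alone, with Mthfd2 (-1.40), Phgdh (-1.40) and Shmt2 (-1.28). Of 24 targets of the stress regulator ATF4 6 fell, 8 when adjusted over the list alone, led by Asns (-2.00). Of 34 genes of MYC-driven ribosome biogenesis 2 fell, also when adjusted over the list alone, Npm1 (-1.20) and Nob1 (-1.07). Of 72 nuclear genes of oxidative phosphorylation 1 rose and 0 fell by limma, and 0 passed over the list alone. Of 34 G2/M genes 1 rose, also over the list alone, the cytokinesis gene Anln (2.61). Of 23 glycolysis genes 0 passed, over all genes or the list alone, with a median of -0.35. The calls of Rpl3, Rps2, Rpl14 and Shmt2 were lost without any library other than GLUT3-deficient replicate 2, those of Phgdh, Npm1 and Nob1 without wild-type replicate 2 or 3 or GLUT3-deficient replicate 1 or 3, that of Mthfd2 without wild-type replicate 2 or GLUT3-deficient replicate 1, and that of Anln without any wild-type library or GLUT3-deficient replicate 1.

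Markers of other cells also differed between the genotypes in Th17 cultures. All 4 tested gamma delta T cell markers rose, with Trdc from 4.46 ± 0.365 to 63.9 ± 15.6 TPM, Trgc2 by 3.49, Trgc4 by 3.12 and Trgc1 by 2.68 on the log2 scale. Of 8 myeloid markers 4 rose, including Tyrobp (2.02) and Fcer1g (2.08). Of 7 markers of CD8 and natural killer cells 2 rose, Klrk1 (2.08) and Klrc1 (1.49), and of 8 red cell and platelet markers 3 rose, including Pf4 (2.92) and Ppbp (1.86). Of 7 B cell markers 1 rose, Igkc (1.39). Adjusted over the list alone 4, 5, 3, 7 and 1 rose. The calls of Tyrobp, Klrk1, Fcer1g and Klrc1 were lost without wild-type replicate 2 or 3, those of Fcer1g, Klrc1, Pf4, Ppbp and Igkc without GLUT3-deficient replicate 1, that of Klrc1 without GLUT3-deficient replicate 3, that of Pf4 without wild-type replicate 2, and those of Ppbp and Igkc without any wild-type library.

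In all, 1009 of 13823 genes passed the test in Th17 cells, 636 higher and 373 lower, and 3453 had an unadjusted p under 0.05. The groups did not overlap for 36.7% of the genes, where chance alone gives 10%. Camera called 21 of 45 lists, 15 up and 6 down: interferon response (adjusted p = 1.7e-18), Th1 genes (2.32e-09), immediate early genes (1.49e-07), the pathogenic program (0.000353), cytokines (0.00163), chemokines (0.00206), ribosomal proteins (9.69e-13, down), serine metabolism (0.00877, down), ATF4 targets (0.00598, down), ribosome biogenesis (0.00206, down) and oxidative phosphorylation (0.00459, down) and G2/M (3.72e-05), but neither glycolysis (0.0567) nor the core Th17 genes (0.511). The myeloid (0.0031), CD8 and natural killer (0.00877) and red cell and platelet (0.000409) markers were called up, and the B cell markers were not called (0.836). None of the 21 held with an estimated correlation: there the interferon, Th1, immediate early, pathogenic and cytokine lists had adjusted p = 0.469, red cell markers adjusted p = 0.637, myeloid and CD8 markers adjusted p = 0.469, and chemokine, ribosomal, serine, ATF4, G2/M and ribosome biogenesis lists adjusted p = 0.795, with oxidative phosphorylation at adjusted p = 0.81. By fry, which asks only for movement on balance in 1 direction, 8 of the 21 lists passed. Its adjusted p was 0.0225 for the interferon and Th1 lists, 0.0145 for immediate early genes, 0.0197 for the pathogenic program and 0.0249 for cytokines. Red cell (0.0636), chemokine (0.0808), ribosomal (0.204), ATF4 (0.211), serine (0.306), G2/M (0.306), ribosome biogenesis (0.517) and oxidative phosphorylation (0.574) lists did not pass by fry. Without GLUT3-deficient replicate 2 oxidative phosphorylation turned up, at a camera adjusted p of 0.464. The count of genes was 109, 2158 or 283 without GLUT3-deficient replicate 1, 2 or 3, and 444, 162 or 132 without wild-type replicate 1, 2 or 3. It was 2933 with all 12 libraries in the model, 1849 with GC and length trends removed and 7465 with weights per library, in a fit that did not converge. The split was 1034 higher and 1124 lower without GLUT3-deficient replicate 2, 147 and 15 without wild-type replicate 2, 117 and 15 without wild-type replicate 3, 1556 and 1377 with all 12 libraries, and 3037 and 4428 in the fit that did not converge. With no filter on low TPM the calls of Wdr54, Il21, Txnip, Slc2a6, Il17re, Shmt2, Rpl3, Rps2, Rpl14 and Igkc were lost, those of Il21 and Slc2a6 were also lost with a pseudocount of 5, those of Rps2 and Rpl14 with voom, and that of Igkc with all 12 libraries.

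GLUT3-deficient Th1 libraries held more transcript of effector cytokines and chemokines than wild-type Th1 libraries. Markers of other cells differed in the same libraries: all 4 tested gamma delta T cell markers rose (median log2 fold change 2.97), and of 7 markers of CD8 and natural killer cells 3 rose and 2 fell. Of the 18 handling-sensitive immediate early genes 13 rose. Ifng rose from 778 ± 317 to 7977 ± 1078 TPM (log2 fold change 3.43), Spp1, which encodes osteopontin, from 4.52 ± 2.02 to 157 ± 18.4 TPM, the costimulatory ligand Tnfsf9 from 14.4 ± 5.81 to 384 ± 31.7 TPM, the interleukin 23 subunit Il23a from 1.86 ± 1.26 to 61.7 ± 15 TPM and the chemokine Ccl3 from 30.4 ± 11.9 to 689 ± 207 TPM. Il22 (3.87), Trdj1 (4.03), Ifi211 (3.97), the lipase Mgll (3.96), Ifi205 (3.84) and Smpdl3b (3.78) completed the 10 largest rises, and those of Trdj1 rest on 21, 21 and 8 reads in the deficient libraries. The largest falls were in Slc2a3, Tnip3 (-3.97), Ly6g (-3.57), Lcp2, an adaptor of T cell receptor signalling (-3.40, from 174 ± 5.85 to 15.6 ± 1.88 TPM), Zfas1 (-2.92), Trib2 (-2.90), Acvrl1 (-2.84), Selenbp1 (-2.82), Ankrd37 (-2.81) and M1ap (-2.69). Limma adjusted p-values of these 20 genes ran from 7.14e-06 to 0.0243, and the rule again took only genes whose groups did not overlap. Wild-type levels varied widely for Acvrl1 (28.1 ± 29.2 TPM), Selenbp1 (114 ± 98.2 TPM) and Ankrd37 (139 ± 131 TPM). Like Slc2a3, these genes were highest in wild-type replicate 1. The call of Selenbp1 was lost without wild-type replicate 2 or with no filter on low TPM.

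Of the key genes, 12 rose and 5 fell in Th1 cells. Tbx21 rose from 112 ± 17.9 to 226 ± 25.6 TPM (limma adjusted p = 0.00199) and Il21 from 60.7 ± 2.16 to 313 ± 35.7 TPM (3.23e-05). Il17a (2.47) and Il17f (1.29) rose from very low levels of 0.217 ± 0.214 and 0.575 ± 0.292 TPM to 7.63 ± 7.07 and 3.04 ± 1.59 TPM, while the interleukin 23 receptor gene Il23r (-1.88) fell. Csf2 (1.28), Txnip (1.63), Hif1a (1.23), Cd4 (0.63) and Ccr6 (0.51) rose as well, all in 3 of 3 libraries. Slc2a1 rose from 333 ± 125 to 567 ± 111 TPM (adjusted p = 0.041), Il2 fell by 1.65 on the log2 scale (0.0409), both with groups that overlapped, and Myc fell by 0.59 (0.0225). The call of Slc2a1 was lost without wild-type replicate 2 or 3 or GLUT3-deficient replicate 1 or 3, that of Il2 without wild-type replicate 1 or 3 or GLUT3-deficient replicate 1 or 2, that of Ccr6 without any library other than wild-type replicate 3, that of Myc without wild-type replicate 2 or GLUT3-deficient replicate 1 or 2, and that of Cd4 without GLUT3-deficient replicate 3. With all 12 libraries in the model the calls of Tbx21, Slc2a1, Cd4, Ccr6 and Myc were lost, and with no filter on low TPM those of Il17a, Il17f, Slc2a1, Ccr6 and Il2. Over all alternatives the adjusted p ran from 0.000776 to 0.233 for Tbx21, from 0.00483 to 0.0506 for Il17a and from 0.0037 to 0.0539 for Il17f. Foxp3, Hk2, Ldha and Acly did not pass, with log2 fold changes from -0.45 to 0.36. Slc2a6 rose from 8.03 ± 2.94 to 25.5 ± 2.41 TPM (adjusted p = 0.00187).

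All 42 ribosomal protein genes fell in Th1 cells, over all genes and over the list alone, with a median log2 fold change of -1.0. Examples were Rpl14 (-1.32), Rplp1 (-1.24), Rpl11 (-1.24) and Rps4x (-1.14). Differences of the 3 deficient Th1 libraries from the wild-type mean rose with exon length across genes (Spearman's rho 0.17, 0.16 and 0.28). Each wild-type Th1 library against the others of its group gave 0.11, -0.21 and 0.06. The falls are given here without removal of that trend. Of 34 genes of ribosome biogenesis 8 fell and 1 rose, with the same counts when adjusted over the list alone, among them Npm1 (-1.24) and Nob1 (-0.96). Of 36 interferon response genes 26 rose and 0 fell, 29 when adjusted over the list alone, with Usp18 (1.79), Irf7 (1.76), Gbp3 (1.73) and Oasl2 (2.25). Of 25 Th1 genes 18 rose and 2 fell, 18 and 3 when adjusted over the list alone, including Lta (2.25) and Ccl5 (3.73). Of 26 cytokine genes 16 rose and 3 fell, 16 and 4 when adjusted over the list alone; Il10 rose from 61.8 ± 4.71 to 462 ± 105 TPM. Of 23 genes of chemokines and migration 11 rose and 3 fell, 12 and 3 when adjusted over the list alone, and Ccl4 led with 3.02. Of 18 immediate early genes, which respond to receptor signals and to handling, 13 rose, also when adjusted over the list alone, with Dusp2 (2.69), Btg2 (2.67) and Dusp1 (2.19).

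Of 34 G2/M genes of the cell cycle 19 rose, 27 when adjusted over the list alone, with Anln (2.53), Kif20a (1.52) and Aurka (1.22). Of 27 genes of the unfolded protein and heat shock responses 14 rose and 2 fell, with the same counts when adjusted over the list alone; Creld2 (1.48), Pdia3 (0.93) and Pdia4 (0.92) rose. Of 24 cholesterol synthesis genes 9 rose and 1 fell, 10 and 1 when adjusted over the list alone, with Acat2 (1.42) and Hsd17b7 (1.09). Of 72 oxidative phosphorylation genes 13 fell and 1 rose, 9 and 1 when adjusted over the list alone, with Atp5g2 (-0.87), Uqcr10 (-0.85) and Ndufb5 (-0.64). Of 14 serine and one-carbon genes 6 fell and 1 rose, 7 and 1 when adjusted over the list alone, with Shmt2 (-0.78), Psat1 (-0.67) and Phgdh (-0.67). Of 24 ATF4 targets 6 fell and 3 rose, 6 and 4 when adjusted over the list alone; Pycr1 (-1.61) and Asns (-1.24) fell. Of 22 glycolysis genes 1 rose, Pfkfb1 (1.84), and 2 fell, Aldoc (-1.46) and Gpi1 (-0.83), or 1 and 0 when adjusted over the list alone. Of 19 core Th17 genes 9 rose and 3 fell, with the same counts when adjusted over the list alone, and of 19 genes of the pathogenic program 11 rose and 1 fell, 11 and 3 when adjusted over the list alone. The call of Aldoc was lost without wild-type replicate 1 or 2 or GLUT3-deficient replicate 1 or 2, that of Gpi1 without wild-type replicate 2 or any GLUT3-deficient library, and that of Phgdh without GLUT3-deficient replicate 1. Those of Aldoc, Gpi1 and Uqcr10 were also lost with all 12 libraries in the model.

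Markers of other cells differed in Th1 cultures too. Trdc rose from 5.49 ± 2.35 to 55.7 ± 11.6 TPM, and Trgc4 (3.04), Trgc2 (2.90) and Trgc1 (2.76) rose with it, so that all 4 tested gamma delta T cell markers passed. Of 7 CD8 and natural killer markers 3 rose, Klrk1 (2.13), Klrc1 (2.77) and Klrd1 (1.72), and 2 fell, among them Cd8a (-0.90), or 5 and 2 when adjusted over the list alone. Of 5 myeloid markers 2 rose, Tyrobp (1.44) and Fcer1g (1.74), and 1 fell, Ly6g, also when adjusted over the list alone, and of 7 red cell and platelet markers 3 rose, 4 when adjusted over the list alone, including Pf4 (2.90) and Ppbp (1.86). Of 9 B cell markers 0 rose and 1 fell by limma, and 0 passed over the list alone.

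In Th1 cells 4220 of 13487 genes passed, 2374 higher and 1846 lower, 1654 of them by over 2-fold, and 5792 had an unadjusted p under 0.05. The higher count than in Th17 cells does not show a larger effect. The median absolute log2 fold change was 0.37 in Th1 and 0.44 in Th17, with a median SE of 0.19 and 0.3. With all 12 libraries in the model, where the groups share 1 spread, 2568 genes passed in Th1 and 2933 in Th17. The groups did not overlap for 47.1% of the genes, against 10% by chance. Camera called 20 of 45 lists, 17 up and 3 down, with adjusted p = 3.53e-24 for ribosomal proteins (down), 1.56e-09 for interferon response, 1.73e-06 for Th1 genes, 0.000691 for the pathogenic program, 1.24e-06 for G2/M, 1.62e-05 for immediate early genes, 0.0006 for cytokines, 0.042 for chemokines, 0.00952 for the unfolded protein response, 0.00795 for cholesterol synthesis, 0.000626 for oxidative phosphorylation (down), 0.00217 for ribosome biogenesis (down) and 0.0166 for red cell and platelet markers. It did not call glycolysis (0.372), serine metabolism (0.0709), ATF4 targets (0.271), core Th17 genes (0.0709), CD8 and natural killer markers (0.13), myeloid markers (0.523) or B cell markers (0.607). None of the 20 held with an estimated correlation: the interferon and Th1 lists had adjusted p = 0.337, cytokines adjusted p = 0.399, the pathogenic program adjusted p = 0.441, ribosomal proteins adjusted p = 0.414, chemokines adjusted p = 0.462, immediate early genes and the unfolded protein response adjusted p = 0.68, G2/M and red cell markers adjusted p = 0.685, oxidative phosphorylation adjusted p = 0.687, cholesterol synthesis adjusted p = 0.712 and ribosome biogenesis adjusted p = 0.733. Fry, which asks only whether the genes of a list move on balance in 1 direction, called 19 lists, 13 of the 20 among them. Its adjusted p was 0.00065 for interferon response, 0.000747 for Th1 genes and 0.00126 for ribosomal proteins. Core Th17 genes (0.00188) and CD8 and natural killer markers (0.00963) also passed by fry. G2/M (0.074), oxidative phosphorylation (0.163) and ribosome biogenesis (0.206) did not. The count of genes was 2594, 2747 or 2728 without GLUT3-deficient replicate 1, 2 or 3, and 2568 with all 12 libraries in the model. With GC and length trends removed 4717 genes passed, 3632 of the 4220 among them. Camera then called 20 lists, 18 of the 20 named above among them.

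The genotype effects of the 2 lineages resembled each other across genes. Over 13070 genes tested in both, the log2 fold changes correlated with Pearson's r = 0.794 and Spearman's rho = 0.783, across genes that are not independent replicates. The comparisons share no library, but wild-type libraries of the same number deviated together. Over all libraries the covariance of the effects was 0.423, and over libraries of different numbers alone, a comparison chosen after seeing the data, it was 0.401, which gives r = 0.753. The numbers for independent lists leave this shared part out. In both lineages 498 genes rose, where independent lists would share 99.4, and 276 fell, where they would share 45.9. Only 3 genes passed in opposite directions, with 136.5 for independent lists. Of the 908 Th17 calls tested in both, 893 had the same sign in Th1 cells. Without Th17 GLUT3-deficient replicate 2 the genes called in both numbered 1400, without Th17 GLUT3-deficient replicate 1 or 3 they numbered 97 or 235, and without Th17 wild-type replicate 1, 2 or 3 they numbered 352, 141 or 113, against 774 with all libraries.

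**Figure D3:**
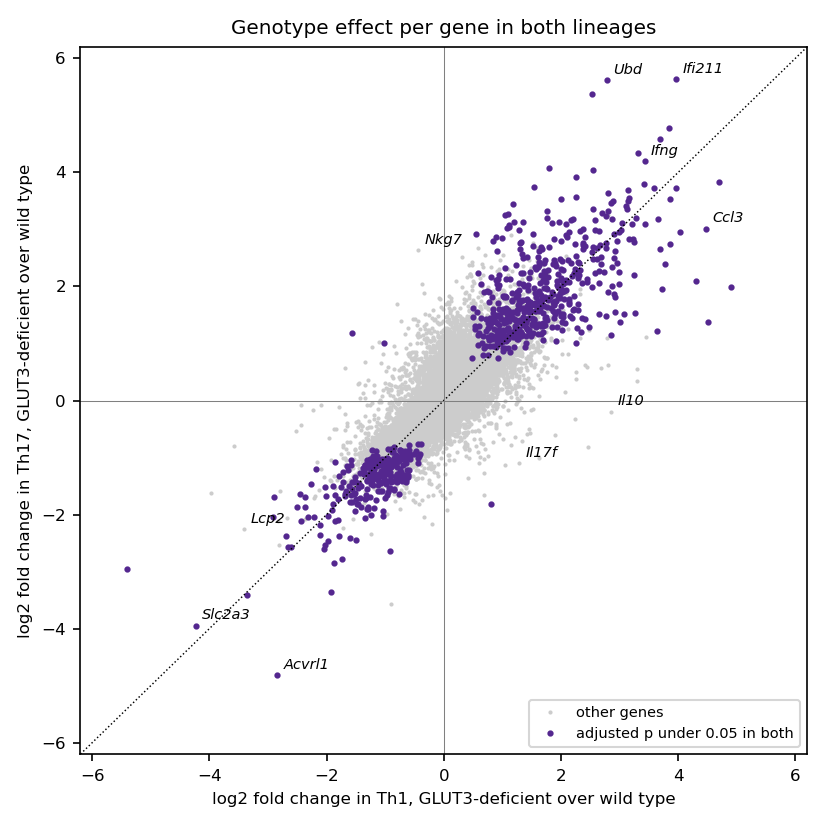
Log2 fold change (GLUT3-deficient over wild type, TPM + 1) of each of 13070 genes in Th1 (horizontal) and Th17 (vertical) cells, with genes that passed in both lineages in purple and a dotted line of equal effects. Of the purple genes 498 rose and 276 fell in both, and 3 lie in opposite quadrants.

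The interaction asked which genes responded to the genotype differently in the 2 lineages, and 93 of 14579 genes passed, 51 with the higher effect in Th17 and 42 in Th1, with 930 at an unadjusted p under 0.05. Il10, an anti-inflammatory cytokine, stood at 56.9 ± 0.550 and 49.8 ± 5.87 TPM in wild-type and deficient Th17 cells and rose from 61.8 ± 4.71 to 462 ± 105 TPM in Th1 cells, a difference of effects of -3.05 ± 0.25 (SE, limma adjusted p = 0.000358, n = 3 per group). Cyp11a1, the first enzyme of steroid synthesis, stood at 19.1 ± 1.96 and 15.1 ± 1.63 TPM in Th17 cells and rose from 5.84 ± 0.765 to 31.2 ± 1.93 TPM in Th1 cells (-2.56, adjusted p = 0.000802). The effect was higher in Th17 for Ccn3, Gja5 and Nkg7. Ccn3 stood at 3.67 ± 0.395 and 80.0 ± 13.9 TPM in Th17 and at 0.070 ± 0.121 and 0.623 ± 0.133 TPM in Th1 (3.50, limma adjusted p = 0.000358). Gja5, a gap junction protein, stood at 1.84 ± 0.241 and 36.1 ± 14.6 TPM in Th17 and at 0 and 0.012 ± 0.021 TPM in Th1 (3.63, adjusted p = 0.000759). At such low Th1 levels the log2(TPM + 1) scale hides most of a change. The differences for Ccn3 and Gja5 therefore do not show that a response was absent in Th1. Nkg7, a cytotoxic granule protein, stood at 23.9 ± 4.64 and 157 ± 46.7 TPM in Th17 against 969 ± 78.2 and 721 ± 122 TPM in Th1 (3.08, adjusted p = 0.00103). Of the 21 key genes 0 passed by limma and 5 had an unadjusted p under 0.05, the smallest adjusted p being that of Il17f (-2.39, adjusted p = 0.0547), which passed without Th17 wild-type replicate 1 or Th1 GLUT3-deficient replicate 3. The count of 93 was 171 without Th17 GLUT3-deficient replicate 2 and 45, 29, 31, 40, 40, 46, 24, 21 and 30 without Th17 wild-type replicate 2 or 3, Th17 GLUT3-deficient replicate 1 or 3, Th1 wild-type replicate 2 or 3, or Th1 GLUT3-deficient replicate 1, 2 or 3. It was 46 with a block per genotype and number, 44 with a pseudocount of 0.1, 145 with GC and length trends removed, 511 with voom and quality weights and 1124 with weights per library, in a fit that did not converge. With voom on the recovered reads it was 67, 53 with the higher effect in Th17 and 14 in Th1. Of the 93 genes, 40 were also called by that fit, 38 with a pseudocount of 0.1 and 63 with voom and quality weights. Each of the voom fits changed the sign of 1 of the 93, so which genes pass depends on the scale.

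The lineage labels were matched by their signature genes in wild type. Compared with Th1 cells, Th17 cells had higher Il17f (log2 difference 9.07), Il17a (4.13), Ccr6 (3.40), Il21 (1.45), Ccl20 (4.64), Gpr15 (4.52), Krt83 (4.33) and Il9 (4.20), and lower Ifng (-7.41), Tbx21 (-4.63), Nkg7 (-5.30), Plac8 (-5.05) and Ms4a4b (-4.76), with limma adjusted p of at most 0.00245. The groups did not overlap for any of them, which the rule required of those that are not key genes. Of 22 core Th17 genes 13 were higher, 15 when adjusted over the list alone, and of 25 Th1 genes 14 were lower, 17 when adjusted over the list alone; both lists held with an estimated correlation (adjusted p = 0.0276). The pathogenic Th17 list was lower in Th17 cells, 8 of 20 genes, 10 when adjusted over the list alone (adjusted p = 0.0276 with an estimated correlation), and of 39 interferon response genes 10 were lower, 14 when adjusted over the list alone (adjusted p = 0.403 with an estimated correlation). In all, 529 of 14579 genes passed in wild type, 270 higher and 259 lower in Th17. Median-of-ratios scaling moved the median of all genes by -0.162 and the split to 213 higher and 373 lower, so directions of small differences depend on the scaling. The count was 1842 with weights per library, in a fit that did not converge, and 309, 349 or 337 without Th17 replicate 2, Th17 replicate 3 or Th1 replicate 3.

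In GLUT3-deficient cells Il17f (6.69), Il17a (2.89) and Ccr6 (2.60) were higher in Th17 and Ifng (-6.65) and Tbx21 (-3.09) were lower, each in all 3 libraries against all 3 and with limma adjusted p of at most 0.00439. Il23r was also higher in Th17 (1.37, limma adjusted p = 0.00317), while Il22, a core Th17 gene, was lower in Th17 than in Th1 cells (-1.80, limma adjusted p = 0.015), at 20.0 ± 3.08 against 75.2 ± 31.5 TPM, both with groups that did not overlap. In wild type neither passed, with Il23r at -0.02 (limma adjusted p = 0.983) and Il22 at -0.67 (0.469). The interaction passed for neither (limma adjusted p = 0.106 and 0.828), so a change of the lineage difference with genotype is not shown. The call of Il22 was lost without Th1 GLUT3-deficient replicate 2 (-1.48, highest adjusted p of all alternatives 0.0832, lowest 9.99e-06). Il21 did not pass there (0.32, limma adjusted p = 0.44), with groups that overlapped. The calls of Il17a and Tbx21 were lost in a fit on the 6 GLUT3-deficient libraries alone, and over all alternatives their adjusted p ran from 1.98e-05 to 0.0706 and from 1.74e-10 to 0.0642. The ranges given here for Il22, Il17a and Tbx21 include the fit with weights per library, which did not converge. Of 14579 genes 861 passed, 488 higher and 373 lower. With median-of-ratios scaling the median moved by -0.157 and the split became 478 higher and 534 lower. The count was 449, 490 or 563 without Th1 replicate 1, 2 or 3, and 7180 with weights per library, in a fit that did not converge.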

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

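The tests of the 3 patterns weighed here were chosen after the results were seen, while the counts over other splits of the libraries were planned.

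The difference between the genotype effects of the lineages passed its test for 5 genes named by rule: Ccn3 (log2 difference 3.50), Gja5 (3.63) and Nkg7 (3.08), with the higher effect in Th17, and Il10 (-3.05) and Cyp11a1 (-2.56), with the higher effect in Th1. The limma adjusted p-values were 0.000358, 0.000759, 0.00103, 0.000358 and 0.000802. The calls of Ccn3 and Gja5 were lost with voom on the recovered reads. Both genes lay below 1 TPM in every Th1 library, where the log2(TPM + 1) scale hides most of a change.

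Camera also found 9 lists whose genotype effects differed between the lineages. The effect was higher in Th17 for interferon response genes (adjusted p = 1.21e-18, 2 of 39 genes passing, 11 when adjusted over the list alone), myeloid markers (0.000177), genes of naive and memory T cells (0.00587), ribosomal proteins (0.0242) and Th2 genes (0.0499). It was lower in Th17 for ATF4 targets (0.0106), core Th17 genes (0.0225), glycosylation genes (0.0499) and B cell markers (0.0499). None of the 9 held with an estimated correlation: interferon response had adjusted p = 0.556, myeloid markers adjusted p = 0.0789 and the others adjusted p = 0.969. The 9 lists became 13, 4 or 5 without Th17 wild-type replicate 1, 2 or 3 and 4 without Th17 GLUT3-deficient replicate 1. Without Th17 GLUT3-deficient replicate 3 the ribosomal proteins turned to the lower effect in Th17 (camera adjusted p = 0.867). By fry 1 list passed, the myeloid markers (adjusted p = 0.00736).

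Other splits of the libraries were fitted in the same way. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. Every other split puts libraries of both real groups on each side. A real difference then widens the spread within groups and lowers the count of genes, so these splits do not show what chance alone would give. For Th17 genotypes the real split gave 1009 genes and the highest other 0, so 1 of 10 splits gave as many, and for lists 3 of 10 did (21, highest other 21). For Th1 genotypes 1 of 10 splits gave as many genes (4220, highest other 0) and 3 of 10 as many lists (20, highest other 26). Between lineages in wild type the splits numbered 1 of 10 for genes (529, highest other 1) and 5 of 10 for lists (16, highest other 23), and in GLUT3-deficient cells 1 of 10 for genes (861, highest other 2). For the interaction 3 of 100 splits gave as many as the 93 genes. The highest other, 5043, exchanges the genotypes within a lineage, so that it counts the effect common to both lineages. The remaining splits mix the genotypes within at least 1 lineage, so the share of 3 of 100 does not measure chance either. As many as the 9 interaction lists came from 78 of 100 splits, with 26 as the highest other, so chance is not excluded for these lists.

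Th17 GLUT3-deficient replicate 2 stood apart, with a median absolute log2 difference from its group of 0.62, and its deviations followed exon length (Spearman's rho across genes 0.59). Removing trends on GC content and length left 0.45, above the highest of the other 11 libraries (0.31), which argues against such a trend as the whole cause. A mixture with wild-type RNA would move genes toward the wild-type level, but the median share of the way was -0.08 over 115 genes (quartiles -0.61 and 0.18). These genes had large changes in Th1 and between wild-type Th17 and the other deficient Th17 libraries. Lcp2 lay far above the upper quartile, at 192 TPM in this library, a share of 0.88. Slc2a3 was also nearer to wild type, at 18.8 TPM against 5.14 and 3.30 TPM in the other deficient Th17 libraries. No biological explanation was tested.

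All 4 tested gamma delta T cell markers rose in GLUT3-deficient cells of both lineages, while of the B cell markers 1 of 7 rose in Th17 and 0 of 9 in Th1. The medians of the marker lists ran from 0.03 for B cells to 3.31 for gamma delta T cells in Th17 and from 0.33 to 2.97 in Th1. They lay further apart than under shuffled membership (larger permutation p = 0.0213 over 10000 draws), so the markers did not rise alike. A lower share of CD4 T cells would raise only markers of the cells present, so this test cannot decide on it. Shuffling also treats members as independent, and the highest list is the gamma delta list that prompted the question. All 10 of 10 expressed variable segments of the gamma and delta receptor loci were higher in every GLUT3-deficient than in every wild-type library, which is consistent with more gamma delta T cells in these cultures. The labels name CD4+ T cells as the source, a selection that would remove most such cells, and transcription of these segments in other T cells, as part of a genotype effect, was not tested.

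By a rule chosen after the values were seen, 24 genes lay under 0.5 TPM in every wild-type and above 1 TPM in every GLUT3-deficient library, and 5 showed the reverse; Ighj2, Trdj2 and Trgj3 among them are short segments with 1 to 10 reads per GLUT3-deficient library. A chromosome segment carried along with the targeted Slc2a3 locus would place them near it, but 0 of the 29 lay within 10 Mb, which argues against it as the source of these 29 and leaves open whether such a segment exists: Necap1, a neighbour of Slc2a3 chosen after its values were seen, stood at 79.6 to 126 TPM in GLUT3-deficient and 7.93 to 12.8 TPM in wild-type libraries, and Usp18 and Cd4 also lie within 10 Mb. Segments of another strain origin elsewhere may be a source: 7 of the 29 had another within 2 Mb (permutation p = 0.03, median of 10000 draws 2). These lay in 2 regions, on chromosome 1 near Slamf8, Fcer1a and Ifi207, which Ifi204, Ifi205 and Ifi211 adjoin, and on chromosome 12 near Gm6626. The draws took expressed genes at random, so they cannot tell such segments from neighbours that share transcripts or regulation. The chromosome 1 region holds interferon-inducible genes, and interferon response genes rose in both lineages. Gh stood at 11.1 to 13.5 TPM in every GLUT3-deficient library, a ratio of 1.22, and at most 0.19 TPM in wild type. A construct with a growth hormone sequence and transcription of the Gh gene itself cannot be told apart, since the tables hold no reads.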

How the results depend on the processing

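Median-of-ratios scaling, voom, array weights, trend removal and the covariance of different numbers were chosen after seeing the data. Of 3803 values of 216 named gene results under alternatives, 3522 kept direction and side of the threshold, 225 lost the call, 49 gained it and 7 reversed. Of 748 for 58 list results these numbered 561, 168, 13 and 6. Array weights did not converge in 4 of 6 fits, those whose values are given below, and depth limits genes near 0.19 to 0.44 TPM. The correlation between lineages ran from 0.744 to 0.806. The cause of the changes below was not tested, except that leaving out libraries lowers their number. The planned median-of-ratios factors inside edgeR, DESeq2 fits and limma-voom with TMM were not run, although reads had been recovered and voom was run on them.

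The 1009 Th17 genes became 2933 with all 12 libraries, 7465 with array weights, 1849 with trends removed, 2120 with trends removed and the replicate block, and 109 to 2158 without 1 library. The 4220 Th1 genes became 1654 over 2-fold, 2568 with all 12 libraries and 2594 to 4587 without 1 library. The 93 interaction genes became 44 with a pseudocount of 0.1, 511 with voom and quality weights, 1124 with array weights, 145 with trends removed and 21 to 171 without 1 library. Lineage counts became 1842 (wild type) and 7180 (deficient) with array weights, and 309 to 403 and 449 to 1219 without 1 library. With trends removed the lineage splits became 249 higher and 435 lower in wild type and 511 and 680 in deficient cells. The 774 genes called in both lineages became 97 to 1400 without 1 library.

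With the replicate number as a block the counts were 1399 (Th17), 4479 (Th1), 85 (interaction), 580 and 960 (lineages), and 46 for the interaction with a block by genotype and number. Same-numbered libraries correlated at 0.16, 0.21 and -0.07 in Th1 and at 0.22, -0.04 and -0.19 between GLUT3-deficient lineages, so there they share only a number. Beyond the Th17 calls of Il17a, Il17f, Tbx21 and Lcp2, the block changed no call of a named gene in the paired comparisons. With the block and an estimated correlation 0, 0, 0 and 3 lists passed.

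Slc2a3 in Th17 lost its call without a filter (-3.95, adjusted p = 0.089) and with a pseudocount of 5 (-3.36, 0.0505), over a range of 2.65e-05 to 0.136, and changed by -4.67 to -3.14 without 1 library. That range of adjusted p includes the array weights fit, which did not converge. Lists passing were 0 (estimated correlation) and 8 (fry) in Th17, 0 and 19 in Th1, 0 and 1 for the interaction, 4 to 13 without 1 library, and 3 and 5 between wild-type lineages. Of the 20 lists called in Th1, 13 were kept by fry. Reversed in Th17 with array weights were Foxp3 (-0.06), Hk2 (-0.27) and Acly (-0.13), and Hk2 with trends removed, with or without the block (-0.07). Without 1 library Hk2 ran from -0.36 to 0.55 and Acly from -0.36 to 1.05. None of these passed as reported. Signed adjusted p-values of reversed lists were 0.912 for B cell markers in Th17 with trends removed (-0.899 to 0.55 without 1 library), 0.567 for fatty acid oxidation in Th1 by fry (-0.982 to 0.985), -0.116 to 0.464 for oxidative phosphorylation in Th17 and -0.867 to 0.687 for ribosomal proteins in the interaction. The sign is that of the direction, so the smallest p-values lie inside these ranges and not at their ends. Over all alternatives, by camera or fry, the unsigned adjusted p of oxidative phosphorylation in Th17 ran from 9.33e-06 to 0.81. That of ribosomal proteins in the interaction ran from 2.67e-21 to 0.999.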

Other observations

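The host genes of small nucleolar RNAs were chosen after their values were seen, so that their counts describe these genes alone, while the lists were fixed in advance.

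Gas5, a host gene of small nucleolar RNAs, whose introns carry guides of ribosomal RNA modification, fell from 723 ± 163 to 126 ± 20.9 TPM in Th1 cells (limma adjusted p = 9.45e-05, n = 3 each) and from 555 ± 118 to 157 ± 57.3 TPM in Th17 cells (0.0205), with every deficient library below every wild-type library. Zfas1, another host gene, fell by 2.92 and 2.04 on the log2 scale. Of 16 such genes tested in Th1 cells 15 fell, and of 15 in Th17 cells 6 fell, Gas5 and Zfas1 included. The Th17 calls of Gas5 and Zfas1 were lost without any wild-type library or GLUT3-deficient replicate 1, and that of Zfas1 also without GLUT3-deficient replicate 3, and both with no filter on low TPM.

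Of 17 regulatory T cell genes 9 rose in Th1 cells, 10 when adjusted over the list alone, and of 18 in Th17 cells 3 rose, 4 when adjusted over the list alone; Foxp3 passed in neither lineage. Of 13 inhibitory receptor genes 7 rose in Th1 cells, also over the list alone, including Pdcd1 (1.28), Entpd1 (1.83) and Cd274 (2.28), and of 14 in Th17 cells 4 rose, 8 when adjusted over the list alone, including Entpd1 (1.62) and Cd274 (2.15). These Th17 calls were lost without any wild-type library or GLUT3-deficient replicate 1, and that of Entpd1 also without GLUT3-deficient replicate 3. Camera called both lists in both lineages, with adjusted p = 0.000626 and 0.00316 in Th1 and 0.00265 and 0.00204 in Th17, and neither held with an estimated correlation (adjusted p = 0.462 and 0.509 in Th1, adjusted p = 0.469 and 0.795 in Th17). Of 21 fatty acid oxidation genes 4 rose and 3 fell in Th1 cells, 5 and 4 when adjusted over the list alone, and 1 rose and 1 fell in Th17 cells, 2 and 5 when adjusted over the list alone. Acadm, a dehydrogenase of medium-chain fatty acids, rose from 61.0 ± 7.21 to 214 ± 15 TPM in Th17 cells, while Eci2 fell by 1.02 on the log2 scale, a call lost without any library other than GLUT3-deficient replicate 2. Camera did not call this list (adjusted p = 0.811 in Th1 and 0.475 in Th17).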
